A study of Linum usitatissimum with 32 samples.

How the data were processed

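Total RNA from internal and external stem tissues of flax, taken from the whole stem or from its upper, middle or lower section, was measured on 32 single-colour NimbleGen arrays. Per the labels, each of the 8 groups held 2 biological replicates with 2 technical arrays each. The deposited values are log2 expression levels, 1 per contig and array, made by the authors with RMA, a method that commonly joins background correction, quantile normalization and a robust summary over probes, per the submitters' processing notes and the file headers. The software and its version are not given in the sources used here, and neither is which arrays were normalized together. Each contig is covered by 8 probe pairs, or fewer for 2 contigs, and a control probe set summarises 5265 random probes. The series' value table held the same values as the per-array files (1536672 of 1536672 identical). The arrays carry 48021 contigs (47901 in the C series and 120 in the S series of identifiers). Of these, 20482 have a similarity match in the array's annotation, 17999 have a matched protein of known length, and 14680 have a descriptive name.

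The 2 technical arrays of a biological replicate were averaged (avearrays), and the biological replicate was the unit of every test. The whole-stem samples (4, residual df 2) and the section samples (12 in 6 groups, residual df 6) were fitted apart with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without covariates. All tests were two-sided, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over all contigs of a comparison, with a threshold of 0.05. The control probe set was left out. Differences and standard errors are on the log2 scale and are given as internal minus external, or as the lower minus the higher section along the stem. Contrasts were internal minus external in the whole stem, at each height and averaged over the heights, each pair of heights within each tissue, and the interaction of tissue with height (lower against upper).

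The main fits, the lists, the rule for named contigs and the first set of alternatives were fixed before the data were examined. Named contigs were, per main comparison, the 8 largest rises and 8 largest falls among contigs that passed, had a descriptive name and had no overlap between the groups' samples, plus the 2 largest changes of each list. The text describes part of them, chosen after their values and alternatives were seen; at single heights these are mostly contigs whose calls held in most alternatives, so that the examples there look more stable than the named contigs as a whole. There were 26 lists, defined by words in the annotation and by Arabidopsis loci, and 22 with at least 5 contigs were tested with camera in limma at its preset correlation of 0.01, with adjustment over the lists of a comparison. Secondary-wall cellulose synthases, primary-wall cellulose synthases and other arabinogalactan proteins matched 0 contigs and xylem differentiation matched 2, so these 4 were not tested. No contig was in over 1 list. Lists were also tested with an estimated correlation and with fry, which asks whether a list's contigs move one way and does not set them against other contigs; no list call held with an estimated correlation.

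The first set was quantile normalization over all arrays, median centring, the series' value table, leaving out the dimmest 25% of contigs, a log2 difference of at least 1, all arrays with the sample as a random block (duplicateCorrelation), either technical array alone, an intensity trend in eBayes, the replicate number as a block, only the compared groups in the fit, 1 contig per gene name in the lists, and each sample left out in turn. Where a group then kept 1 sample, that sample was assumed to vary like the other groups. Chosen after seeing the data were array weights, the chip number series and an array code number found in the files as covariates, quantile normalization and median centring in the list tests, each chip series alone, fits of tissue alone within the section samples of array code 2 and within the others, only contigs with known protein length with and without their length trend, and the whole-stem internal samples counted as 1. Chip numbers fell into 2 series over the sections, and 1 array of middle external replicate 1 lay outside them. Whether equal replicate numbers mark paired samples was checked by correlating replicate differences between groups.

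The fits were tested on 48021 simulated contigs, 200 changed. A log2 change of 2 was recovered in 71% of changed contigs in the whole stem, 22% in the upper section, 33% between lower and upper internal tissue, 90% in the section average and 0% in the interaction, and a change of 1 in 0%, 1%, 0%, 39% and 0%. In each case 0 to 8 unchanged contigs, a list shifted by 0.5 and 0 other lists were called. Correlated contigs were not tested.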

Results

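Transcript levels were measured in the stem of flax (Linum usitatissimum), a crop grown for its oil-rich seed and for the long cellulose-rich bast fibres that lie in the outer part of the stem. The internal part of such a stem carries the xylem, whose walls become lignified, and the external part carries bast fibres, phloem, green cortex and the waxy epidermis. Total RNA from the internal and the external tissues of greenhouse plants was labelled with Cy3 and hybridised to 1-colour NimbleGen arrays. The tissues came either from the whole stem or from its upper, middle or lower section, which made 8 groups. Each group had 2 biological replicates with 2 technical arrays apiece, 32 arrays in all. Technical arrays were averaged, so that n = 2 per group, and the comparison of tissues averaged over the 3 heights set 6 internal against 6 external samples. No label ties the biological replicates to separate plants beyond that name, so the p-values measure the spread between these samples.

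The arrays carried 48021 contigs, which are assembled transcript sequences, and 20482 of them (42.7%) had a sequence similarity match in the array's annotation. Contigs are named here by that match, several contigs can match the same protein, and none was placed on a genome. The number of arrays limits the precision. Random control probes had a log2 level of 6.03 to 6.77 on the section arrays, 6.51 to 6.83 on the whole-stem external arrays and 6.68 to 7.39 on the whole-stem internal arrays. Between 88.5% and 99.0% of contigs lay above that level on section arrays, 88.5% to 94.0% on whole-stem external arrays and 79.7% to 92.2% on whole-stem internal arrays. Across contigs, which are not independent replicates, technical arrays of the section samples correlated at r = 0.943 to 0.994, whereas those of the whole-stem internal samples correlated at 0.855 and 0.845. Biological replicates correlated at 0.811 in the middle internal group, the lowest value, and at 0.993 in the upper internal group, the highest.

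**Figure D1:**
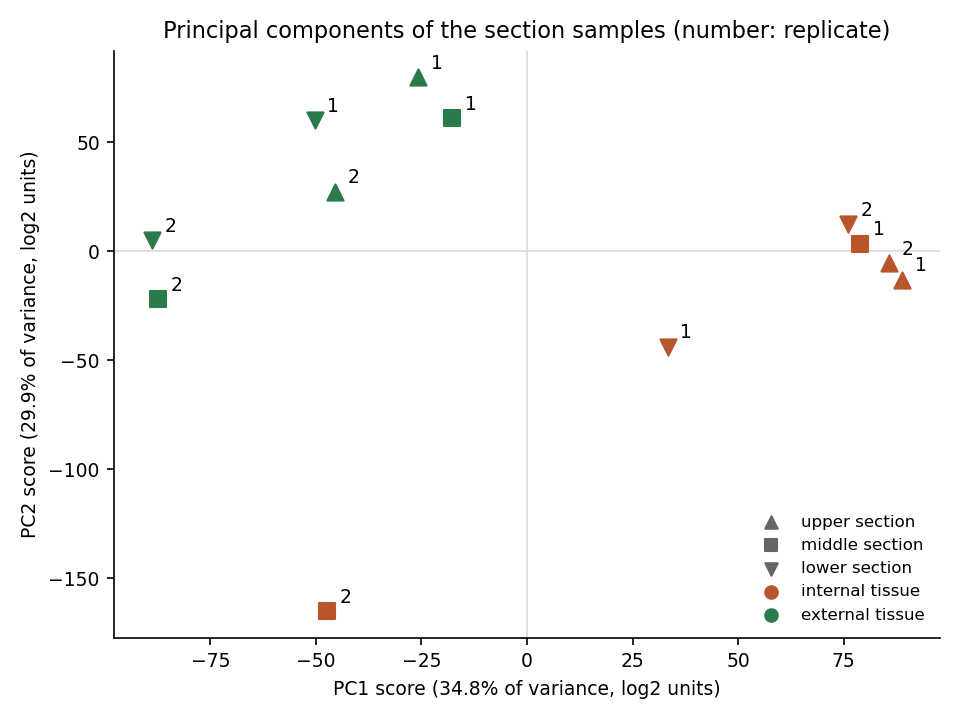
Each point is one biological replicate of the stem sections on the first and second principal components of the log2 levels of all contigs, which hold 34.8% and 29.9% of the variance. The middle internal replicates lie far apart, and their levels correlated at r = 0.811 across contigs.

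Which transcripts set the internal apart from the external tissue of the stem sections was tested first, with the tissue difference averaged over the 3 heights (6 against 6 samples). The largest difference in favour of internal tissue among named contigs was that of GENOLIN_C1591, matched to a Decreased apical dominance protein, a family of carotenoid-cleaving enzymes that limit branching: 4.97 on the log2 scale (SE 0.20, adjusted p = 6.0e-06), from a mean level of 8.25 in external to 13.21 in internal samples. A germin-like protein (GENOLIN_C2113, 4.24, SE 0.24), a pinoresinol-lariciresinol reductase, an enzyme of lignan synthesis (GENOLIN_C3993, 4.01, SE 0.20), a beta glucosidase (GENOLIN_C3983, 3.97, SE 0.24) and xylem serine proteinase 1 (GENOLIN_C25478, 3.94, SE 0.15) were also higher in internal tissue. External tissue had the higher levels of a proline-rich APG isolog (GENOLIN_C5237, -4.09, SE 0.27), of WAX2, which takes part in making cuticular wax (GENOLIN_C822, -4.04, SE 0.52), of peroxidases (GENOLIN_C953, -3.93, SE 0.29, and GENOLIN_C1253, -3.79, SE 0.41) and of a 3-ketoacyl-CoA synthase, which lengthens the fatty acids of waxes (GENOLIN_C29726, -3.89, SE 0.59). In limma, 6085 contigs passed an adjusted p of 0.05, 3304 higher in internal and 2781 higher in external tissue.

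Genes of lignified wall formation were higher in internal section tissue. Of 16 laccase contigs, whose enzymes polymerise lignin, 11 were higher and 0 lower over all contigs tested (11 and 1 adjusted over the list alone), with a list median of 2.28; examples were GENOLIN_C3323 (3.65, SE 0.48) and GENOLIN_C4612 (3.35, SE 0.20). Of 84 contigs of the lignin pathway, which makes the monolignols, 37 were higher and 4 lower (40 and 6 adjusted over the list alone), with a median of 0.55. Caffeoyl-CoA 3-O-methyltransferase GENOLIN_C2255 was higher by 3.57 (SE 0.21), whereas the 4-coumarate--CoA ligase-like contig GENOLIN_C25237 was lower (-3.15, SE 0.25). Of 7 xylan synthesis contigs, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 1.65; they included GENOLIN_C10850 (3.63, SE 0.44) and GENOLIN_C1776 (2.52, SE 0.25), matched to Arabidopsis proteins that build the xylan backbone and its reducing end. Of 9 dirigent and lignan contigs 3 were higher and 0 lower by either adjustment, with a median of 0.09. The lists passed the camera test against all other contigs at adjusted p = 2.5e-07 for laccases, 1.1e-09 for the lignin pathway, 1.8e-06 for xylan synthesis and 0.0264 for the dirigent list. These calls were lost at adjusted p = 0.148, 0.148, 0.190 and 0.190 with an estimated correlation, in the same order. The dirigent call was also lost without middle internal replicate 1 (adjusted p = 0.0973), with 1 contig per name (0.599, with the median at -0.07) and over contigs of known protein length with each sample's length trend removed (0.0998). Its median was 0.01 and 0.19 without upper external replicates 1 and 2, 0.18 without middle external replicate 1, 0.05 and 0.16 without middle internal replicates 1 and 2 and 0.05 without lower internal replicate 2. It was 0.14 without dim contigs, 0.15 and 0.61 within the first and the second series of chip numbers, and 0.04 with the array code, a number in the files that 5 of the section samples share, as a covariate. Within those 5 samples it was -0.08 (adjusted p = 0.0356, with camera's direction still higher) and within the other 7 it was 0.24. The laccase median was 1.36 within the first chip series and 0.93 within the 5 samples, and that of the lignin pathway 1.05 without dim contigs.

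Cellulose synthases, tubulins and actins, and the cell cycle and histone list were also higher in internal section tissue. Of 32 cellulose synthase contigs 10 were higher and 1 lower by either adjustment (median 0.25), with GENOLIN_C2533 at 2.52 (SE 0.20) and GENOLIN_C2422 at 2.46 (SE 0.17). Of 44 tubulin and actin contigs 7 were higher and 0 lower (9 and 1 adjusted over the list alone; median 0.52), among them a beta-tubulin (GENOLIN_C5037, 2.05, SE 0.22). Of 134 cell cycle and histone contigs 26 were higher and 0 lower (32 and 0 adjusted over the list alone; median 0.35), led by a kinesin light chain-like contig (GENOLIN_C9893, 2.92, SE 0.14) and a kinesin (GENOLIN_C6221, 1.68, SE 0.16); kinesins are motor proteins that also serve outside cell division. Kinesins made up 35 of those contigs and 14 of the 26, a split made after the values were seen. Of the other 99 contigs 12 were higher and 0 lower (median 0.29, camera adjusted p = 1.7e-05, or 0.262 with an estimated correlation). The 3 lists passed camera at adjusted p = 1.7e-05, 2.0e-06 and 2.3e-08, and were lost at adjusted p = 0.262, 0.148 and 0.148 with an estimated correlation. Of 68 pectin-remodelling contigs 19 were higher and 5 lower (21 and 9 adjusted over the list alone; median 0.12), with a polygalacturonase-like contig (GENOLIN_C4285, 2.30, SE 0.11) and a pectate lyase (GENOLIN_C32427, 2.29, SE 0.17) on top. Of 27 fasciclin-like arabinogalactan protein contigs, cell-surface proteins common in fibres and xylem, 9 were higher and 7 lower (11 and 7 adjusted over the list alone; median 0.64), and contigs GENOLIN_C1109 and GENOLIN_C5556, both matched to member 11, were higher by 3.36 (SE 0.27) and 3.09 (SE 0.28). Camera gave adjusted p = 0.0339 for pectin remodelling and 0.0336 for the fasciclin-like list, both lost at adjusted p = 0.596 and 0.60 with an estimated correlation. With the chip number series as a covariate both calls were lost (adjusted p = 0.107 and 0.0699). They were also lost within the first series (0.459 and 0.0590), within the second (0.816 and 0.0828), after quantile normalization (0.0521 and 0.0828) and with the length trend removed (0.371 and 0.184). The pectin call was also lost without upper external replicate 2 (adjusted p = 0.251), upper internal replicate 2 (0.0533), middle internal replicate 1 (0.0513) or 2 (0.0626), lower external replicate 2 (0.0538) or lower internal replicate 2 (0.0529), and with the array code as a covariate (0.0881), within the 5 samples of that code (0.0815) and within the other 7 (0.114). The fasciclin-like call was lost without upper external replicate 2 (0.0856), middle external replicate 2 (0.0741), middle internal replicate 1 (0.209), lower external replicate 2 (0.102) or lower internal replicate 2 (0.0503), without dim contigs (0.109), with 1 contig per name (0.262) and within the 5 samples of the array code (0.0661). Its median was 0.43 without middle external replicate 2, 0.33 without middle internal replicate 1 and 0.16 within those 5 samples. The pectin median was 0.05 without upper external replicate 2, 0.07 without either middle external replicate, 0.03 within either chip series, 0.04 with the length trend removed, 0.06 within the 5 samples, 0.51 without dim contigs and 0.45 with 1 contig per name. The cellulose synthase median was 0.41 without middle external replicate 1 and 0.42 within the second chip series, and within the 5 samples the cell cycle and tubulin medians were 0.22 and 0.30.

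External section tissue had the higher levels of cuticle, photosynthesis, peroxidase and lipid transfer genes. Of 20 cuticle and wax contigs 15 were lower and 1 higher in internal tissue by either adjustment (median -2.91), and 3-ketoacyl-CoA synthase 1 GENOLIN_C29546 stood at -3.68 (SE 0.38). Of 338 photosynthesis contigs 70 were lower and 3 higher (114 and 4 adjusted over the list alone; median -0.47), among them a chlorophyll a/b binding protein (GENOLIN_C15759, -3.18, SE 0.26) and Rubisco activase (GENOLIN_C602, -2.67, SE 0.31). Of 123 peroxidase contigs 29 were lower and 4 higher (35 and 4 adjusted over the list alone; median -0.30). Of 52 lipid transfer protein contigs 22 were lower and 11 higher (27 and 14 adjusted over the list alone; median -0.50); GENOLIN_C6325 stood at -3.58 (SE 0.17) and GENOLIN_C817 at 3.85 (SE 0.23). Of 49 chitinase-like contigs 11 were lower and 3 higher (15 and 3 adjusted over the list alone; median -0.28), with GENOLIN_C188 at -2.65 (SE 0.49). The 5 lists passed camera at adjusted p = 6.7e-13, 9.7e-18, 1.7e-07, 1.7e-05 and 0.000159. They were lost at adjusted p = 0.0820, 0.0820, 0.148, 0.165 and 0.379 with an estimated correlation. The lipid transfer median was -1.18 without dim contigs, -1.52 with 1 contig per name, -0.88 within the second chip series and -0.24 within the 5 samples of the array code, and the chitinase-like median -0.49 without dim contigs and -0.48 within the second series.

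The other 8 lists tested did not pass camera in the section average. Of 18 phloem contigs 1 was higher and 1 lower by either adjustment (median -0.20, adjusted p = 0.430), and a sucrose transport protein was higher in internal tissue (GENOLIN_C17072, 1.78, SE 0.18). Beta-galactosidases (21 contigs, 2 higher and 4 lower by either adjustment, median 0.21, adjusted p = 0.948) and auxin response genes (43 contigs, 6 higher and 3 lower, 8 and 4 adjusted over the list alone, median 0.06, adjusted p = 0.369) had members on both sides, and the auxin median turned to -0.01 after quantile normalization. Expansins and xyloglucan enzymes had 7 contigs higher and 8 lower of 74 (8 and 9 adjusted over the list alone; median -0.11, adjusted p = 0.487). Of 65 aquaporin contigs 8 were higher and 4 lower (12 and 9 adjusted over the list alone; median 0.07, adjusted p = 0.908), with a tonoplast intrinsic protein at -3.43 (GENOLIN_C6338, SE 0.24) and aquaporin 2 at 1.32 (GENOLIN_C3045, SE 0.20). Of 31 pathogenesis-related contigs 2 were higher and 1 lower by either adjustment (median -0.12, adjusted p = 0.275), the thaumatin-like GENOLIN_C25674 at 3.79 (SE 0.40). Of 157 stress and heat shock contigs 1 was higher and 9 lower (0 and 2 adjusted over the list alone; median -0.06, adjusted p = 0.144), and of 657 ribosomal protein contigs 11 were higher and 30 lower (1 and 7 adjusted over the list alone; median 0.11, adjusted p = 0.289).

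**Figure D2:**
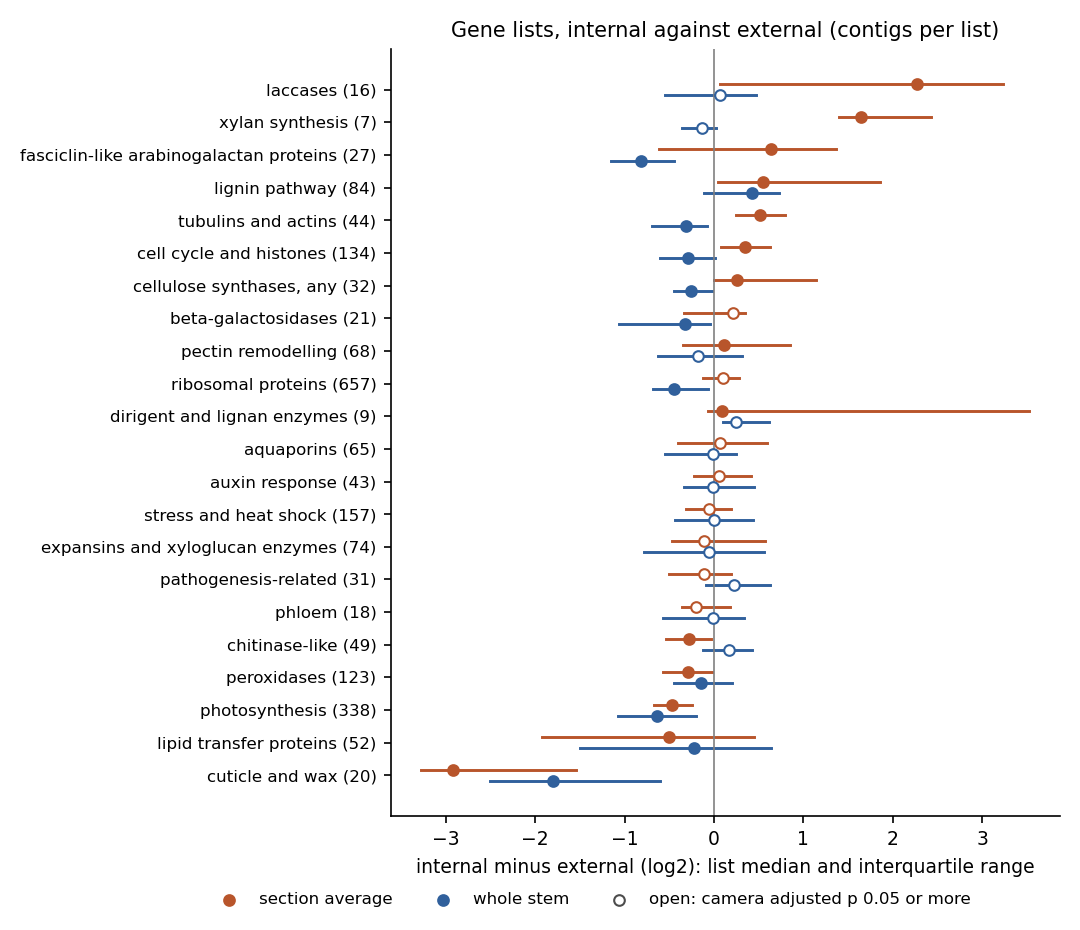
Points are the median log2 difference, internal minus external, over the contigs of each gene list (number in brackets) and lines the interquartile range over contigs, for the section average and the whole stem; open points did not pass camera. Laccases stood at 2.28 in the sections and 0.07 in the whole stem, cuticle and wax genes at -2.91 and -1.80.

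The section-average count fell to 3235 and 3368 without upper internal replicates 1 and 2 and to 3747 without lower internal replicate 2. Chip numbers in the files fell into 2 series, apart from 1 array of middle external replicate 1, a sample counted with the first; with the series as a covariate 6228 contigs passed, in limma 0 passed among the 7 samples of the first series (3818 at an unadjusted p under 0.05) and 28764 among the 5 samples of the second, a fit with a single pair of replicates to measure spread. Of the 6085 contigs, 99.9% had the same direction within the first series and 99.8% within the second, but these contigs were chosen on the same samples. The list medians within the first and the second series were 1.36 and 2.31 for laccases, 0.62 and 0.65 for the lignin pathway, -3.05 and -2.64 for cuticle and wax and -0.43 and -0.43 for photosynthesis. The first series pairs the tissues in the middle and lower sections and the second in the upper and lower, so these medians cover unlike heights; in the lower section the laccase medians were 1.53 and 1.78. With the array code as a covariate 11307 contigs passed. Fits of tissue alone mix it with height. They passed 619 contigs among the 5 samples of that code (390 higher, 229 lower) and 7462 among the other 7. Of these, 614 and 4630 were among the 6085. Of the 6085 contigs 99.8% had the same direction within that code and 100% among the others, with laccase medians of 0.30 and 2.23 in the middle and 1.53 and 1.78 in the lower section. Middle internal replicate 2 stood apart from the other internal samples, and its list medians lay below those of replicate 1 for xylan synthesis (-1.30), laccases (-0.85), cellulose synthases (-0.70), fasciclin-like proteins (-0.70), tubulins (-0.56) and the lignin pathway (-0.52). They lay above those of replicate 1 for pathogenesis-related genes (0.52), ribosomal proteins (0.41), chitinase-like genes (0.30), peroxidases (0.30) and photosynthesis (0.27). Without it 8279 contigs passed in the section average, and without replicate 1 of that group 8746.

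**Figure D3:**
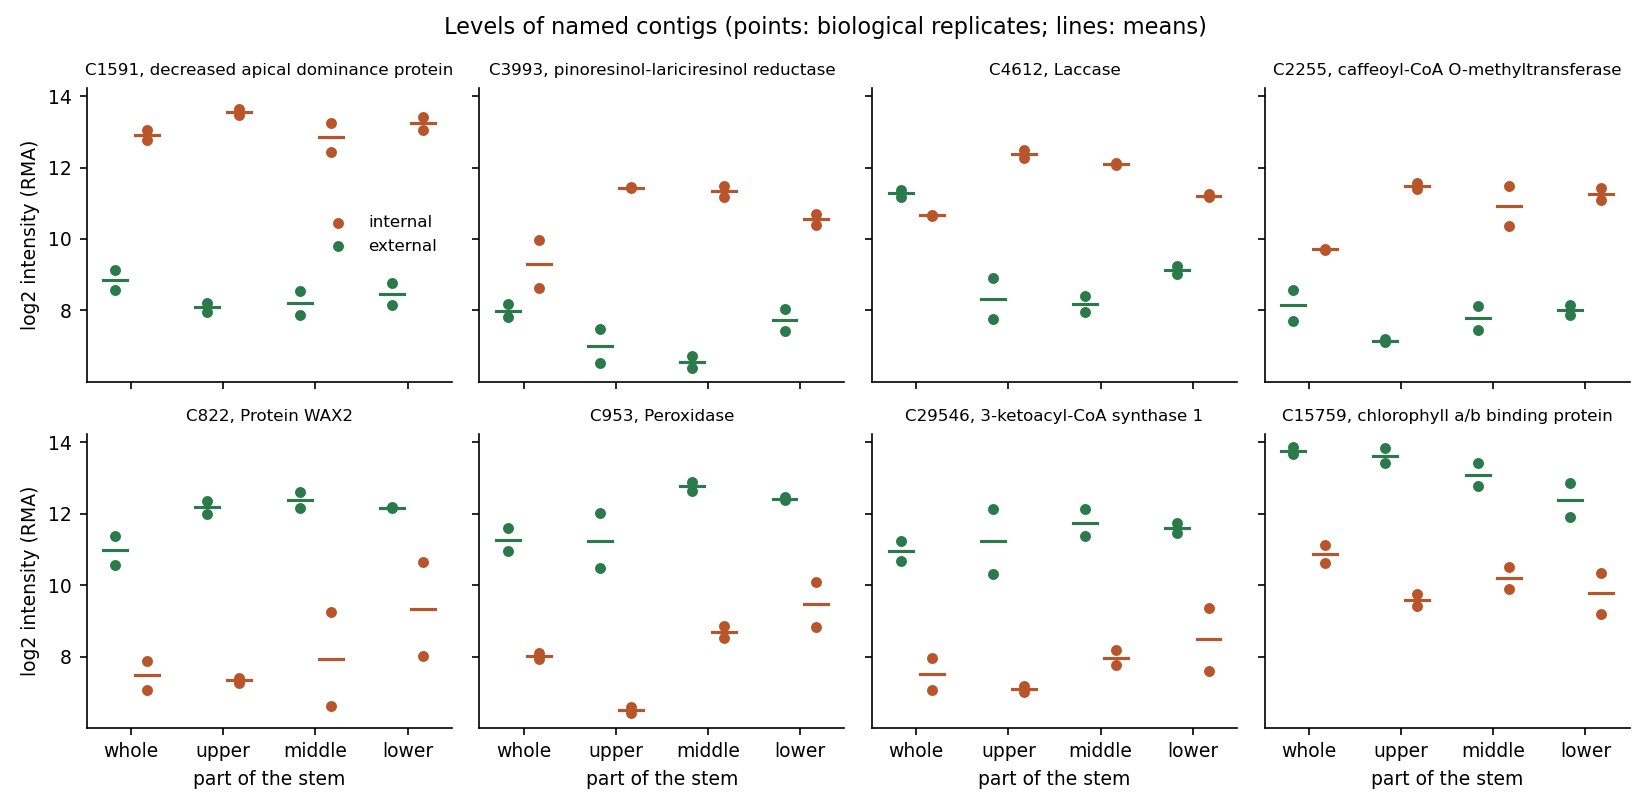
Log2 levels of selected named contigs in each biological replicate, with bars for the group mean, in internal and external tissue of each section and of the whole stem. GENOLIN_C1591 was higher in internal tissue by 4.97 in the section average and by 4.04 in the whole stem.

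Tissues were also compared at each height. In the upper section, contigs higher in internal tissue included GENOLIN_C1591 (5.48, SE 0.35), the germin-like GENOLIN_C2113 (4.83, SE 0.41), the pinoresinol-lariciresinol reductase GENOLIN_C2534 (4.47, SE 0.32), caffeoyl-CoA 3-O-methyltransferase GENOLIN_C2255 (4.33, SE 0.37) and a class IV chitinase, an enzyme that cuts chitin (GENOLIN_C53904, 3.99, SE 0.39). Contigs higher in upper external tissue included the APG isolog GENOLIN_C5237 (-5.01, SE 0.47), an orcinol O-methyltransferase (GENOLIN_C32155, -4.76, SE 0.44), lipid transfer proteins (GENOLIN_C6325, -4.75, SE 0.30, and GENOLIN_C353, -4.68, SE 0.37), and the chlorophyll a/b binding GENOLIN_C15759 (-4.04, SE 0.46). In limma, 1950 contigs passed (1149 higher, 801 lower in internal tissue; n = 2 per group, spread shared over all 6 section groups). The count was 958 without upper external replicate 2, 518 and 541 without upper internal replicates 1 and 2, and 2993 without either middle internal replicate. It was 3402 over all arrays with the sample as a random block and 3705 with the array code as a covariate. The internal level of GENOLIN_C5237 (6.42) lay within 0.5 of the random probes, so that background limits the size of its difference. With only the second chip series, which holds 1 upper external and both upper internal samples, 20387 passed; in the first series the upper section had no internal sample.

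In the middle section GENOLIN_C817, of the protease inhibitor and lipid transfer family (4.94, SE 0.39), the pinoresinol-lariciresinol reductase GENOLIN_C3993 (4.79, SE 0.35), xylem serine proteinase 1 GENOLIN_C25478 (4.44, SE 0.25) and the laccase GENOLIN_C4612 (3.92, SE 0.35) were higher in internal tissue. The peroxidase GENOLIN_C953 (-4.08, SE 0.51), a harpin-induced protein (GENOLIN_C36508, -3.86, SE 0.35) and the 3-ketoacyl-CoA synthase GENOLIN_C8414 (-3.42, SE 0.29) were higher in external tissue. In limma, 1416 contigs passed (801 higher, 615 lower). With only the middle groups in the fit, of the first chip series apart from 1 array, limma passed 0 contigs (3259 at an unadjusted p under 0.05), so that none of these calls held there; with the chip series as a covariate 1610 passed. The external level of GENOLIN_C3993 (6.55) lay near the random probes (6.32). The count was 856 without either upper internal replicate, 496 and 561 without middle external replicates 1 and 2, and 6209 without middle internal replicate 1. It was 2744 over all arrays with a random block, 3483 with the array code as a covariate and 433 with array weights.

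In the lower section GENOLIN_C1591 (4.78, SE 0.35), a beta-1,4-xylosidase, an enzyme that trims xylan (GENOLIN_C17729, 3.67, SE 0.33), an adenine phosphoribosyltransferase-like contig (GENOLIN_C34250, 3.49, SE 0.36) and the kinesin light chain-like GENOLIN_C9893 (2.67, SE 0.24) were higher in internal tissue. A major latex protein-like contig (GENOLIN_C1407, -3.29, SE 0.31) was higher in external tissue. In limma, 1793 contigs passed (904 higher, 889 lower), and after quantile normalization 1937 (696 higher, 1241 lower). Every sample moved this count: it was 3211 without either upper external replicate, 495 without either upper internal, 1116 without either middle external, 4600 without either middle internal, 190 and 113 without lower external replicates 1 and 2, and 124 and 268 without lower internal replicates 1 and 2. With the chip series as a covariate 1888 passed, within the first series 0 in limma (2258 at an unadjusted p under 0.05) and within the second 23793. Over all arrays with a random block 3957 passed, with the array code as a covariate 6606, with array weights 8175, with only the lower groups in the fit 4956 and with technical array 1 alone 1034.

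At all 3 heights 419 contigs passed as higher in internal tissue, 224 as higher in external tissue and 0 in mixed directions. Of the 6085 contigs, chosen on the average over these heights, 5862 (96.3%) had the same direction at every height, which that choice favours. The upper and middle sections shared 628 contigs higher in internal tissue (19.2 for independent lists) and 447 higher in external tissue (10.3). The heights share no samples but share an estimate of spread. Upper, middle and lower list medians were 3.36, 1.25 and 1.64 for laccases and -3.12, -3.11 and -2.47 for cuticle and wax.

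**Figure D4:**
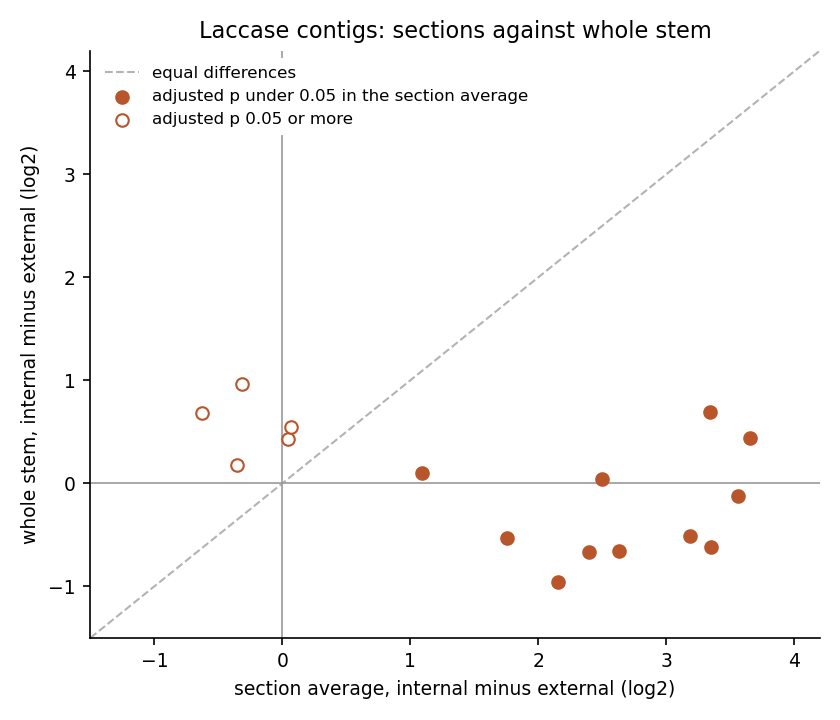
Log2 difference, internal minus external, of each of the 16 laccase contigs in the section average (horizontal) and in the whole stem (vertical); filled points passed limma in the section average, and the dashed line marks equal differences. The list medians were 2.28 and 0.07.

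In the whole stem (2 against 2 samples) GENOLIN_C1591 was again higher in internal tissue (4.04, SE 0.33, adjusted p = 4.8e-05), as were a terpene synthase-like contig (GENOLIN_C15447, 3.20, SE 0.33), a receptor-like protein kinase (GENOLIN_C43801, 3.03, SE 0.31) and a nodulin family protein (GENOLIN_C133, 2.95, SE 0.32). External tissue had the higher levels of lipid transfer proteins (GENOLIN_C5052, -4.76, SE 0.32, and GENOLIN_C6325, -4.62, SE 0.36), a peroxidase (GENOLIN_C864, -4.28, SE 0.38), an RD22-like protein (GENOLIN_C5596, -4.13, SE 0.32) and lipoxygenase LOX1, which oxidises fatty acids (GENOLIN_C1268, -3.86, SE 0.40). Of 18 phloem contigs, the sucrose transport protein GENOLIN_C17072 was higher (2.62, SE 0.32) and sucrose transporter 6 lower in internal tissue (GENOLIN_C9940, -2.67, SE 0.34). Internal levels of GENOLIN_C6325 (7.02) and GENOLIN_C864 (7.39) lay near the random probes (7.04), as did the external level of GENOLIN_C43801 (7.16 against 6.68), so that background limits the size of these differences. In limma, 1150 contigs passed (335 higher, 815 lower in internal tissue). The count was 699 and 518 without external replicates 1 and 2, 753 and 2243 without internal replicates 1 and 2, and 2761 over all 8 arrays with the chip series as a covariate and the sample as a random block. Internal replicates (means of 2 arrays) differed by SD 0.552, their single arrays by 0.761 and 0.826. Counted as 1, the replicates left 697 contigs. Quantile normalization left 523, technical arrays 1 and 2 alone 124 and 356, and all arrays with a random block gave 2097.

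Cuticle and photosynthesis genes were lower in whole-stem internal tissue. Of 20 cuticle and wax contigs 13 were lower and 0 higher by either adjustment (median -1.80), with the 3-ketoacyl-CoA synthase GENOLIN_C29726 at -3.95 (SE 0.38). Of 338 photosynthesis contigs 54 were lower and 0 higher (117 and 1 adjusted over the list alone; median -0.63), with GENOLIN_C15759 at -2.89 (SE 0.32). Of 27 fasciclin-like contigs 6 were lower and 0 higher (12 and 0 adjusted over the list alone; median -0.82), among them GENOLIN_C17603, matched to member 7 (-2.56, SE 0.32). Of 21 beta-galactosidase contigs, enzymes that trim galactan side chains of the fibre wall, 5 were lower and 0 higher (6 and 0 adjusted over the list alone; median -0.33), among them GENOLIN_C26549 (-2.37, SE 0.35) and GENOLIN_C1998 (-2.26, SE 0.32). Of 123 peroxidase contigs 10 were lower (15 adjusted over the list alone; median -0.15) and of 657 ribosomal protein contigs 12 (1 adjusted over the list alone; median -0.44), with 0 higher. These 6 lists passed camera at adjusted p = 5.9e-18, 4.9e-24, 3.8e-11, 0.000126, 0.0026 and 9.7e-13. They were lost at adjusted p = 0.280, 0.111, 0.313, 0.436, 0.313 and 0.280 with an estimated correlation. The beta-galactosidase call was also lost with 1 contig per name (0.776), and its median was -0.52 after quantile normalization. That median was -0.54 without external replicate 1 and -0.62 without dim contigs. The peroxidase call was lost with the length trend removed (0.512), and its median was -0.07 and -0.23 without external replicates 1 and 2 and -0.22 without dim contigs. The fasciclin-like median was -0.45 without internal replicate 1.

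The lignin pathway list was higher in whole-stem internal tissue (median 0.43, camera adjusted p = 0.000341). That call was lost at adjusted p = 0.623 with an estimated correlation, at 0.177 without internal replicate 2 (median 0.15) and at 0.124 with 1 contig per name (median 0.28). Of its 84 contigs 4 were higher and 0 lower (12 and 2 adjusted over the list alone), one of them a 4-coumarate:CoA ligase (GENOLIN_C8865, 1.97, SE 0.32). Of 52 lipid transfer contigs 6 were higher and 15 lower (9 and 17 adjusted over the list alone; median -0.22, camera adjusted p = 0.00555). That call was lost at adjusted p = 0.313 with an estimated correlation, at 0.0557 without internal replicate 2 and at 0.367 with the length trend removed, and the median was -0.09 after quantile normalization, -0.07 and -0.15 without external replicates 1 and 2, -0.15 without internal replicate 1 and -0.34 with 1 contig per name. Cellulose synthases (0 higher, 2 lower by either adjustment; median -0.26, adjusted p = 0.00555) and tubulins (median -0.32, adjusted p = 0.000341) were lower, each lost at adjusted p = 0.623 with an estimated correlation and without internal replicate 1 (adjusted p = 0.102 and 0.0811, with both medians at -0.12). The tubulin median was -0.53 without internal replicate 2. After quantile normalization the cellulose synthase median was -0.07 and the call was lost (adjusted p = 0.288), as it was with 1 contig per name (0.124) and with the length trend removed (0.423). Cell cycle genes were lower as a list (median -0.29, adjusted p = 0.000187; adjusted p = 0.280 with an estimated correlation and 0.136 with the length trend removed). Limma passed 0 contigs of the tubulin and cell cycle lists over all contigs and over the list alone.

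The other 11 lists did not pass camera in the whole stem. Limma passed 0 of 16 laccase (median 0.07, adjusted p = 0.937), 9 dirigent and lignan (0.25, 0.162), 7 xylan synthesis (-0.13, 0.401), 49 chitinase-like (0.16, 0.134) and 31 pathogenesis-related contigs (0.23, 0.162). Phloem contigs (1 higher, 2 lower, 1 and 3 adjusted over the list alone) had a median of -0.02 (adjusted p = 0.497). Pectin remodelling (1 higher, 2 lower by either adjustment; median -0.18, adjusted p = 0.115), expansins (1 and 10, 9 and 17 adjusted over the list alone; -0.06, 0.162) and aquaporins (1 and 3, 1 and 5 adjusted over the list alone; -0.01, 0.134) had more members lower than higher. Stress genes (1 higher, 2 lower, 3 and 2 adjusted over the list alone) had a median of 0.00 (adjusted p = 0.801) and auxin response genes (0 higher, 1 lower by either adjustment) of -0.01 (0.937). The medians of the xylan, phloem, stress and auxin lists changed sign after quantile normalization.

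Whole stem and section average, fitted apart, both passed 702 contigs, 678 in the same and 24 in opposite directions. They shared 194 contigs higher in internal (23.0 for independent lists) and 484 higher in external tissue (47.2). Of the 1150 whole-stem contigs, 1005 (87.4%) had the same sign in the section average. Differences correlated at r = 0.79 across those contigs and 0.21 (Spearman rho -0.027) across all, which are not independent replicates.

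**Figure D5:**
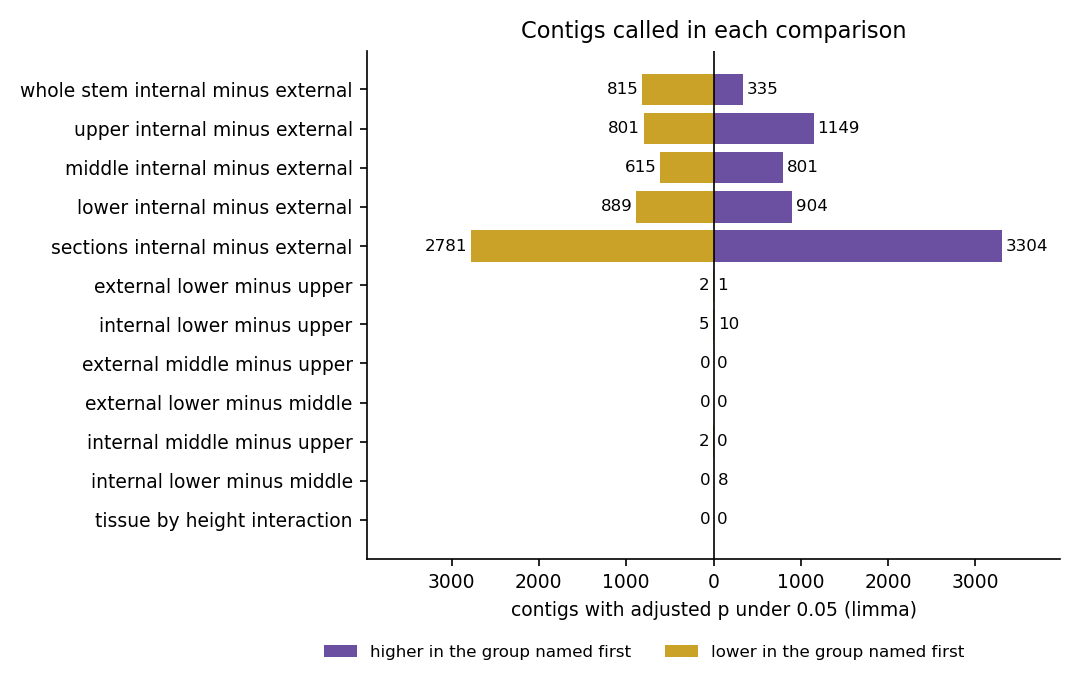
Bars are the numbers of contigs that passed limma at an adjusted p of 0.05 in each comparison, higher and lower in the first-named group. The section average gave 3304 and 2781, the whole stem 335 and 815.

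How each tissue differed along the stem was tested next. In internal tissue, lower against upper section (2 against 2 samples), a branched-chain amino acid aminotransferase (GENOLIN_C32531, 3.37, SE 0.31, adjusted p = 0.00928) and a ripening-induced protein (GENOLIN_C301, 3.09, SE 0.26) were higher in the lower section. A terpineol synthase, which makes a volatile terpenoid (GENOLIN_C23674, -3.26, SE 0.20, adjusted p = 0.0022), the class IV chitinase GENOLIN_C53904 (-3.39, SE 0.39), a beta-1,3-glucanase (GENOLIN_C2582, -2.68, SE 0.25) and tubby-like protein 8 (GENOLIN_C20392, -2.29, SE 0.24; lower section level 6.63 against 6.16 for random probes) were lower there. Limma passed 15 contigs (10 higher, 5 lower). It passed 0 without any one of the upper internal or lower internal replicates, 8 without any one of the middle external or lower external replicates and 60 without either middle internal replicate; with the chip series as a covariate 15 passed, and within the second series 3754. Over all arrays with a random block 252 passed, with the array code as a covariate 129, with array weights 889, with only the compared groups 316 and with technical array 2 alone 7. Between lower and middle internal tissue 8 contigs passed, 8 higher and 0 lower, named here after their values were seen. Those with a match were an N-hydroxylating cytochrome P450 (GENOLIN_C52259, 4.22, SE 0.47), threonine deaminase, which starts isoleucine synthesis (GENOLIN_C33111, 3.83, SE 0.25), the aminotransferase GENOLIN_C32531 (3.80, SE 0.31), a cytochrome P450 of the CYP71E family (GENOLIN_C2430, 3.44, SE 0.38) and a dimethylaniline monooxygenase-like protein (GENOLIN_C16662, 2.36, SE 0.25). That count was 0 without lower internal replicate 1, 4 without lower internal replicate 2 or without any one upper internal or lower external replicate, 5 without either middle external replicate and 5268 without middle internal replicate 1; it was 7 with the chip series as a covariate and 0 within the first series (309 at an unadjusted p under 0.05). It was 87 over all arrays with a random block, 28 with the array code as a covariate, 5 after quantile normalization, 3 with array weights or technical array 2 alone, and 0 with only the compared groups (865). Between middle and upper internal tissue 2 passed, the glucanase GENOLIN_C2582 (-2.85, SE 0.25; middle level 6.62 against 6.28 for random probes) and the terpineol synthase GENOLIN_C23674 (-2.22, SE 0.20). That count was 0 without any one sample other than the middle internal replicates, 7593 and 1 without middle internal replicates 1 and 2, 5 after median centring (2 higher, 3 lower) and 0 with the chip series as a covariate (2896 at an unadjusted p under 0.05). It was 103 over all arrays with a random block, 13 with the array code as a covariate, 7 with an intensity trend, 1 after quantile normalization or without dim contigs, and 0 with array weights (2844 at an unadjusted p under 0.05), only the compared groups (2011) or technical array 1 (4329) or 2 (3720) alone.

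As lists, laccases (median -0.89, camera adjusted p = 1.1e-09), cell cycle genes (-0.32, 5.8e-18), photosynthesis genes (-0.24, 2.1e-11) and aquaporins (-0.40, 5.6e-09) were lower in lower than in upper internal tissue, and cuticle and wax genes were higher (0.92, 6.3e-10). Each of these 5 was lost at adjusted p = 0.101 with an estimated correlation. Limma passed 0 contigs of these 5 lists over all contigs; adjusted over the list alone, 4 laccases and 3 cell cycle contigs were lower and 5 cuticle contigs higher. Pectin remodelling (median -0.34, camera adjusted p = 6.9e-09), expansins (-0.32, 6.0e-12), pathogenesis-related genes (-0.26, 8.2e-08), tubulins (-0.30, 1.6e-05), fasciclin-like proteins (-0.69, 4.4e-05) and chitinase-like genes (-0.13, 2.1e-05) were also lower. These were lost at adjusted p = 0.152, 0.228, 0.249, 0.173, 0.277 and 0.277 with an estimated correlation; of their contigs the class IV chitinase passed over all contigs, and 2 pectin, 2 pathogenesis-related and 3 chitinase-like contigs were lower adjusted over the list alone. Xylan synthesis (-0.68, adjusted p = 0.0034), cellulose synthases (-0.16, 0.0112) and beta-galactosidases (-0.28, 0.0204) were lower with 0 contigs passing limma by either adjustment, and were lost at adjusted p = 0.373, 0.483 and 0.127 with an estimated correlation. Without lower internal replicate 1 the xylan and beta-galactosidase calls were lost (adjusted p = 0.0740 and 0.212), without upper internal replicate 1 that of cellulose synthases (0.149), and with the chip series as a covariate that of xylan synthesis (0.136). With the array code as a covariate the calls of xylan synthesis (0.264), cellulose synthases (0.481, with the median at 0.02) and beta-galactosidases (0.0683) were lost. The last was also lost without dim contigs (0.0518), with the length trend removed (0.0564) and with 1 contig per name (0.251), as was the chitinase-like call with 1 contig per name (0.122). Without lower internal replicate 1 the medians were 1.59 for cuticle, -0.57 for laccases, -0.22 for pectin remodelling, -0.44 for pathogenesis-related genes, -0.44 for xylan synthesis, -0.10 for cellulose synthases and -0.14 for beta-galactosidases. Without lower internal replicate 2 they were 0.32 for cuticle, -0.27 for cellulose synthases and -0.45 for beta-galactosidases. With the array code as a covariate they were -0.51 for laccases, -0.09 for fasciclin-like proteins, -0.14 for pectin remodelling, -0.15 for expansins, -0.17 for tubulins and -0.18 for both xylan synthesis and beta-galactosidases. With the chip series as a covariate they were -0.55 for laccases, -0.28 for xylan synthesis, -0.33 for fasciclin-like proteins, -0.12 for pectin remodelling, -0.10 for expansins, -0.22 for cell cycle genes, -0.26 for aquaporins and -0.17 for both pathogenesis-related genes and beta-galactosidases. Without dim contigs they were -0.50 for expansins and -0.64 for aquaporins, and with 1 contig per name -0.55 for laccases and -0.36 for cellulose synthases. The other 8 lists did not pass, and the lipid transfer list had a median of -0.09 while camera's direction was higher.

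In external tissue, lower against upper section, limma passed 3 contigs: a PDR-like ABC transporter (GENOLIN_C17756, -2.82, SE 0.28, adjusted p = 0.0475) and GENOLIN_C44375 (-2.80, SE 0.28) were lower in the lower section, and GENOLIN_C25908 (3.09, SE 0.31), which has no match, was higher. The last 2 were named after their values were seen. Lower section levels of the transporter were 6.80 and 6.65, close to the random probes (6.54 and 6.63 in those samples), so that background limits the size of its difference. The count was 0 without any one of the 12 section samples, 0 with the chip series as a covariate (5867 at an unadjusted p under 0.05), 0 within the first series (2513) and 8717 within the second. It was 158 over all arrays with a random block, 17 with the array code as a covariate, and 0 after median centring (5156), with array weights (5042), only the compared groups (4695) or technical array 2 alone (8035). Limma passed 0 contigs between middle and upper (763 at an unadjusted p under 0.05) and between lower and middle external tissue (5733). Over all arrays with a random block these counts were 2 and 26. With the array code as a covariate 1 contig passed between lower and middle external tissue.

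As lists, lignin pathway genes (median 0.55, camera adjusted p = 4.1e-08), laccases (0.90, 2.7e-06), lipid transfer proteins (0.53, 1.2e-06), chitinase-like genes (0.52, 4.5e-06), pathogenesis-related genes (0.58, 4.6e-06) and peroxidases (0.13, 0.00176) were higher in lower than in upper external tissue. They were lost at adjusted p = 0.346, 0.346, 0.346, 0.375, 0.375 and 0.375 with an estimated correlation. Limma passed 0 contigs of these lists over all contigs; adjusted over the list alone 7 lignin pathway contigs and 2 laccases were higher, 9 chitinase-like contigs were higher and 2 lower, and 1 peroxidase was lower. The peroxidase call was lost without dim contigs (0.0612, with the median at -0.01) and with 1 contig per name (0.115), and its median was 0.22 after quantile normalization. Without upper external replicate 2 the medians were 0.24 for the lignin pathway, 0.36 for laccases, 0.24 for chitinase-like and 0.22 for pathogenesis-related genes; without upper external replicate 1 they were 0.85 for the lignin pathway, 1.35 for laccases and 0.32 for peroxidases. The lignin pathway median was 0.32 without lower external replicate 1 and 0.36 with 1 contig per name. That of peroxidases was 0.20 without lower external replicate 2, 0.06 with 1 contig per name and 0.07 with the length trend removed, and that of lipid transfer proteins then 0.35. Another 7 lists passed but each lost its call without a single sample. Without upper external replicate 2 these were photosynthesis (median -0.30, adjusted p = 0.000447; 0.0927 without that sample), pectin remodelling (0.16, 0.00176; 0.324, with the median at -0.03), expansins (0.23, 0.0046; 0.725, with the median at -0.09), ribosomal proteins (0.10, 0.0106; 0.725), aquaporins (0.22, 0.0065; 0.524, with the median at -0.07) and stress genes (0.12, 0.0028; 0.282, with the median at -0.01). Cell cycle genes (-0.20, 0.0109) lost theirs without upper external replicate 1 (0.548) or lower external replicate 2 (0.189), and expansins, ribosomal proteins and aquaporins also without lower external replicate 1 (0.606, 0.280 and 0.134). Without dim contigs the calls of pectin remodelling (0.0612), expansins (0.0528), cell cycle (0.0612) and aquaporins (0.234, with the median at -0.13) were lost. With 1 contig per name those of pectin remodelling (0.0617), ribosomal proteins (0.318) and aquaporins (0.195) were lost. The ribosomal call was lost with the length trend removed (0.332, with the median at -0.04). After quantile normalization the cell cycle call was lost (0.0520, with the median at -0.09), and the ribosomal and stress medians were 0.20 and 0.21. Without upper external replicate 1 the medians were 0.50 for pectin remodelling, 0.51 for expansins, 0.20 for ribosomal proteins, 0.36 for aquaporins, 0.26 for stress and -0.12 for cell cycle genes, and without replicate 2 -0.19 for photosynthesis and -0.33 for cell cycle genes. Without lower external replicate 1 they were 0.07 for pectin remodelling, 0.01 for expansins, 0.01 for ribosomal proteins, -0.07 for aquaporins and 0.06 for stress genes, and without replicate 2 0.30, 0.48 and 0.16 for the first 3. In the order photosynthesis, pectin remodelling, expansins, ribosomal proteins, aquaporins, stress and cell cycle, the calls were lost at adjusted p = 0.375, 0.381, 0.573, 0.613, 0.375, 0.375 and 0.447 with an estimated correlation. The other 9 lists did not pass, and the phloem list had a median of -0.10 while camera's direction was higher.

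Whether the tissue difference itself changed from the upper to the lower section was tested as an interaction. Laccases (median -1.68, camera adjusted p = 1.0e-11), pathogenesis-related genes (-0.84, 4.8e-11), expansins (-0.72, 1.7e-10), lignin pathway genes (-0.60, 5.4e-08), pectin remodelling (-0.59, 1.7e-09), aquaporins (-0.54, 1.3e-08) and chitinase-like genes (-0.46, 1.7e-09) had a lower internal-minus-external difference in the lower section. They were lost at adjusted p = 0.212 with an estimated correlation, or 0.343 for expansins. Without upper external replicate 2 the medians were -0.33 for the lignin pathway, -0.36 for expansins, -0.33 for pectin remodelling and -0.29 for aquaporins; without replicate 1 they were -0.91 for the lignin pathway, -0.92 for aquaporins and -0.71 for chitinase-like genes. Without lower external replicate 1 they were -0.37 for expansins and -0.36 for aquaporins, and with the chip series as a covariate -0.43 for expansins and -0.37 for pectin remodelling. Adjusted over the list alone 8 laccases, 6 chitinase-like, 2 pectin, 1 aquaporin and 1 pathogenesis-related contigs passed, all lower. In limma 0 contigs passed over all contigs (3214 at an unadjusted p under 0.05), 0 with the chip series as a covariate (2381) and 8070 within the second chip series, while the first holds no upper internal sample. With the array code as a covariate 9 passed, with array weights 5 and over all arrays with a random block 37.

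Another 7 lists passed the interaction test but lost the call in one or more of the alternatives. Xylan synthesis (median -0.88, adjusted p = 0.0202) lost it without upper external replicate 2 (0.122), lower external replicate 1 (0.195), lower internal replicate 1 (0.10) and with the chip series as a covariate (0.0675). Lipid transfer proteins (-0.51, 0.0086) lost it without upper external replicate 2 (0.199), as did stress genes (-0.15, 0.0050; 0.160, with the median at 0.02) and ribosomal proteins (-0.11, 0.0048; 0.181), the last also without lower external replicate 1 (0.0839). Cuticle and wax genes, whose difference was less negative in the lower section (0.67, 0.0191), lost it without upper external replicate 1 (0.193) or lower internal replicate 2 (0.555). Cell cycle genes (-0.20, 0.0037) lost it without lower internal replicate 1 (0.0810). Auxin response genes (0.14, 0.0359) lost it without upper external replicate 1 (0.0908), upper internal replicate 1 (0.0513), lower external replicate 1 (0.0753) or lower internal replicate 1 (0.0810). The calls of these 7 lists were lost at adjusted p = 0.524 for xylan synthesis, 0.623 for ribosomal proteins, 0.212 for auxin response and 0.413 for the others with an estimated correlation. With 1 contig per name the calls of xylan synthesis (0.207), lipid transfer (0.887), cuticle (0.148), cell cycle (0.173), ribosomal (0.0553) and auxin lists (0.264) were lost. The lipid transfer median was then -0.08 while camera's direction turned to higher. After quantile normalization those of cuticle (0.106, median 0.38) and auxin (0.133, median 0.06) were lost. The ribosomal and stress medians were then -0.23 and -0.26. With the array code as a covariate the xylan (0.0820) and auxin calls (0.172) were lost. With the length trend removed the lipid transfer (0.135), cuticle (0.0593) and ribosomal calls (0.628, with the median at 0.03) were lost. Without dim contigs the lipid transfer call was lost (0.104). Without single samples medians ranged from -1.44 without lower external replicate 2 to -0.46 without upper external replicate 2 for xylan synthesis and from 0.15 to 1.23 without lower internal replicates 2 and 1 for cuticle and wax. Without upper external replicates 1 and 2 they were -0.32 and -0.05 for cell cycle genes, -0.26 and -0.02 for ribosomal proteins and 0.25 and 0.23 for auxin response, and without the first -0.31 for stress genes. With the chip series as a covariate they were -0.56 for xylan synthesis, -0.31 for lipid transfer proteins, -0.06 for cell cycle genes, -0.07 for ribosomal proteins, -0.04 for stress genes and 0.25 for auxin response. The other 8 lists did not pass.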

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

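The tests of a faulty array, of external tissue, of the chip series, of array noise and of internal tissue of all kinds in the whole-stem external samples, and the comparison of the whole stem with the sections, were chosen after the results were seen.

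Among the 6 internal section samples, middle internal replicate 2 had a mean correlation of 0.828 with the others, against 0.934 for the next lowest, a gap of 0.914 of the whole range above Dixon's critical value for 6 samples. Chance flags about 1 in 20 groups. Its 2 technical arrays correlated at 0.982, which argues against a faulty array. Of the lists lower in internal tissue, cuticle and wax stood at -0.26 against replicate 1 and the other 4 at 0.12 to 0.30, with all contigs at 0.11. Middle external tissue would need a share of 55.5% to lower the laccase median as measured (-0.85), and that share would raise the 278 contigs higher in external tissue of the upper and lower sections by a median of 1.64 (quartiles 1.18 and 2.12). Their median was 0.19 (quartiles -0.23 and 0.50), which argues against external tissue as the cause of the lower laccases; a small share is neither shown nor excluded. Its difference from replicate 1 fell with protein length (Spearman rho -0.318 across contigs, -0.222 to 0.202 in other section pairs). With that trend removed the gap was 0.922 of the range (0.941 before, on the same contigs). So loss of long transcripts is not the whole cause. A difference between the plants or positions sampled stays open and was not tested.

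The whole-stem and the section tissue differences differed at 1373 contigs (435 higher, 938 lower in the whole stem; 845 after quantile normalization), and in 12 lists by camera, 0 with an estimated correlation (smallest adjusted p = 0.160). The laccase median was lower in the whole stem (-2.56, adjusted p = 0.209 with an estimated correlation), with differences of -3.15 to -2.04 over the 4 pairings of whole-stem samples. These pairings share samples and the list was singled out for this difference, so noise of those arrays is neither shown nor excluded. The difference hardly followed protein length (rho -0.0433). After joint quantile normalization the laccase contigs of whole-stem internal samples differed from section internal samples by a median of -0.196 (-0.50 and -0.07 in replicates 1 and 2). The list's median levels were 10.4 and 10.9, a difference of -0.485. Whole-stem external samples stood at 10.7 and section external samples at 8.50. Lignifying tissue left in the whole-stem external samples is a candidate explanation that rests on this comparison. Of the 419 contigs higher in internal tissue at all 3 heights, 22.2% (93) kept the larger part of their difference in the whole stem, and 84 passed as higher there, so that internal tissue of all kinds in those samples is neither shown nor excluded; plants of another age are an untested alternative.

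In 14 lists the tissue difference itself differed between the lower and the upper section by camera's interaction test, with medians of -1.68 for laccases, -0.88 for xylan synthesis, -0.84 for pathogenesis-related genes, -0.72 for expansins, -0.60 for the lignin pathway, -0.59 for pectin remodelling, -0.54 for aquaporins, -0.51 for lipid transfer proteins, -0.46 for chitinase-like genes, -0.20 for cell cycle genes, -0.15 for stress genes, -0.11 for ribosomal proteins, 0.67 for cuticle and wax and 0.14 for auxin response. With an estimated correlation 0 of the 14 passed (smallest adjusted p = 0.212), and with fry 0 (smallest adjusted p = 0.157). The calls for xylan synthesis, lipid transfer, cuticle, cell cycle, ribosomal, stress and auxin lists were also lost in one or more of the other alternatives, among them single samples left out.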

How the results depend on the processing

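Array weights, scaling in the list tests, array-code and chip covariates and single chip series were chosen after seeing the data. So were fits of tissue alone within array-code samples or the others, known-length contigs with or without trend, and whole-stem internal samples counted as 1. Over all alternatives 6015 values of named contigs stayed past the threshold, 964 did not and 0 reversed. Their rule favoured large changes without overlap, so reversal was unlikely. Of 1398 list values 1176 held, 207 no longer passed and 15 turned. In lower against upper external tissue the median turned without upper external replicate 2 for pectin remodelling (-0.0308), expansins (-0.0893), ribosomal proteins (-0.0017), aquaporins (-0.0742) and stress genes (-0.0128). In the same order their highest values, all without upper external replicate 1, were 0.503, 0.506, 0.203, 0.364 and 0.256. The median also turned for aquaporins without lower external replicate 1 (-0.0663), for peroxidases (-0.0062) and aquaporins (-0.134) without dim contigs, and for ribosomal proteins with the length trend removed (-0.0448). It also turned for dirigent enzymes in the section average with 1 contig per name (-0.0744) and within the 5 array-code samples (-0.0785, adjusted p = 0.0356, camera's direction unchanged), the only one past the threshold, for cellulose synthases in lower against upper internal tissue with the array-code covariate (0.0231), and in the interaction for ribosomal proteins with the length trend removed (0.0296) and stress genes without upper external replicate 2 (0.0192, against a lowest value of -0.314 without upper external replicate 1). For lipid transfer proteins in the interaction with 1 contig per name only camera's direction turned, with the median still below 0 (-0.0768). The series' value table changed nothing, being identical. Scaling moved the median of all contigs by less than 0.1 but moved list medians by more, as in whole-stem cellulose synthases (-0.26 to -0.07 after quantile normalization). Camera then called 10, 12, 13, 14 and 13 lists in the 5 comparisons, and 11, 14, 13, 14 and 14 after median centring. Signal over background limits the whole-stem internal arrays most, with 79.7% of contigs above the random probes on the dimmest; low levels there, and on section arrays near their random probes, bound how large a difference can appear. Unless stated, the cause was not tested.

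Leaving out single samples gave 518 to 2243 contigs in the whole stem, 518 to 2993 upper, 496 to 6209 middle, 113 to 4600 lower, 3235 to 8746 in the section average, 0 to 0 for lower against upper external, 0 to 60 for lower against upper internal, 0 to 7593 for middle against upper internal, 0 to 5268 for lower against middle internal, and 0 to 0 for both other external pairs and for the interaction. Lists ranged from 10 to 14 in the whole stem, 12 to 15 in the sections, 7 to 14 for external and 14 to 15 for internal lower against upper, and 11 to 16 in the interaction.

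With the replicate number as a block the counts were 1970 in the whole stem, 1918, 1394 and 1366 at the 3 heights, 6008 in the section average, 0 and 13 for lower against upper external and internal, 2 for middle against upper internal, 5 for lower against middle internal and 0 elsewhere; list counts were 11, 14, 13, 14 and 14. Replicate differences of groups correlated between -0.584 and 0.759, with both signs, so equal numbers were not taken to pair samples. Among upper, middle and lower external and middle internal tissue all 6 correlations were above 0 (0.278 to 0.759); replicate 2 has the shared array code there.

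Whole stem: quantile normalization 523, all arrays with duplicateCorrelation 2097, technical arrays 1 and 2 alone 124 and 356, chip covariate over all arrays 2761, internal samples counted as 1 697. All arrays with duplicateCorrelation gave 3402 upper, 2744 middle, 3957 lower, 158 and 252 for external and internal lower against upper, 2 and 26 for external middle against upper and lower against middle, 103 and 87 for the internal pairs and 37 in the interaction. With the array-code covariate these were 3705, 3483, 6606, 17, 129, 0, 1, 13, 28 and 9, and 11307 in the section average. Tissue alone, mixed with height, gave 619 within the 5 samples of that code. Array weights gave 433 middle, 8175 lower, 0 external and 889 internal lower against upper, 0 and 3 for the other internal pairs and 5 in the interaction. Only the groups compared gave 0 middle, 4956 lower, 0 and 316 for external and internal lower against upper, and 0 for both other internal pairs. Contigs of known length, fewer by construction, gave 1298 upper, 932 middle, 3458 in the section average, 1 and 27 for lower against upper and 11 for internal middle against upper; with the trend removed the last 4 were 3680, 0, 30 and 7. The first chip series alone, with fewer samples, gave 0 middle, lower, section average, external lower against upper and internal lower against middle, and the second, with 1 residual degree of freedom, 20387 upper, 23793 lower, 28764 average, 8717 and 3754 for lower against upper and 8070 in the interaction.

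Technical array 1 alone gave 1034 lower and 0 for internal middle against upper, and technical array 2 alone 0 and 7 for external and internal lower against upper, 0 for internal middle against upper and 3 for internal lower against middle. A log2 difference of at least 1 left 2839 in the section average. Median centring and the chip covariate each gave 0 for external lower against upper, and 5 and 0 for internal middle against upper, where height and chip series cannot be told apart. Internal middle against upper was also 1 after quantile normalization, 1 without dim contigs and 7 with a trend; internal lower against middle was 5 after quantile normalization. With an estimated correlation 0 lists passed in each of the 5 comparisons; fry, which does not set a list against other contigs, gave 15 in the section average, 1 in the whole stem and 0 for both lower against upper pairs and the interaction. With 1 contig per name 8 interaction lists passed.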

Other observations

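The tests of name words, of array-code samples and their chip series were chosen after the results were seen.

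Words in contig names were tested for enrichment among contigs that passed in the section average or in the whole stem (Fisher's exact test over 345 words, against 14680 named contigs; contigs are not independent). Names with the word secondary, mostly secondary-wall glycosyltransferases, were higher in internal tissue in 11 of 15 contigs and lower in 0 (adjusted p = 1.1e-06), such as GENOLIN_C3061 of family 47 (3.82, SE 0.32) and GENOLIN_C7526 of family 8D (3.67, SE 0.19). In the whole stem these stood at -0.13 and 0.03 and did not pass. Against 9.91% of all named contigs, more contigs than by chance also passed as higher among carboxypeptidases (11 of 21, 1 lower, adjusted p = 7.2e-05), receptors (36 of 154, 11 lower, 5.5e-05), coatomer subunits of vesicle coats (11 of 23, 0 lower, 0.000211), nodulin-like proteins (11 of 25, 2 lower, 0.000456) and S-adenosylmethionine enzymes, which supply methyl groups (17 of 61, 0 lower, 0.00182). Examples were serine carboxypeptidase 1 (GENOLIN_C15334, 3.57, SE 0.59), an ethylene receptor (GENOLIN_C7357, 2.32, SE 0.24), a nodulin-like protein (GENOLIN_C59333, 2.73, SE 0.19) and S-adenosylmethionine synthetase (GENOLIN_C43463, 3.52, SE 0.45). Their whole-stem differences were 0.89, 0.92, 2.18 and -0.25, of which only that of the nodulin-like protein passed. The 3 coatomer contigs with the largest section differences, GENOLIN_C5209, GENOLIN_C11053 and GENOLIN_C6080 (0.88 to 1.07), stood at -0.66, -0.89 and -0.41 there and did not pass.

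Against 7.21% of all named contigs, fructose-bisphosphate enzymes of carbon metabolism were lower in internal tissue in 11 of 20 contigs and higher in 0 (adjusted p = 2.7e-06), with an aldolase at -3.23 (GENOLIN_C3734, SE 0.23) in the sections and -2.09 in the whole stem. Of 184 cytochromes 34 were lower (2.1e-05) and 13 higher; examples are a cytochrome P450 at 3.14 (GENOLIN_C3459, SE 0.22; 0.80 in the whole stem, not passed) and CYP86A24 (GENOLIN_C45570, -2.96, SE 0.46; -1.06 in the whole stem, not passed), and names with the word major were lower in 9 of 24 and higher in 0 (0.000894), of which 8 were among the 12 major latex protein contigs, such as GENOLIN_C779 (-3.29, SE 0.19; -2.91 in the whole stem). Names with the word nitrate were lower in whole-stem internal tissue in 4 of 15 contigs and higher in 0 (adjusted p = 0.0163), against 2.98% of all named contigs, with a nitrate reductase, the first enzyme of nitrate assimilation, at -2.65 (GENOLIN_C38610).

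Section samples whose array code ends in 2 (upper, middle and lower external replicate 2, middle internal replicate 2 and lower internal replicate 1) deviated from their group partners in a like way, with r = 0.278 to 0.759 over 10 pairs across contigs. Whole-stem replicates 2 carry the same number, but their deviations correlated with these at -0.324 to 0.197, so the number does not go with a like deviation there. The middle groups, of 1 chip series apart from 1 array, had the highest value (0.759, or 0.737 without that array). There the series is not the source. In the other groups it goes with the code and is not excluded. With each sample's length trend removed, the mean correlation was 1.02 times that before (0.50 against 0.491), which argues against a loss of long transcripts. A shared day or plant batch is another candidate source that no label records. With the array code as a covariate the section average passed 11307 contigs.

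Chance was tested with 100 splits of the 12 section samples into 6 and 6, blind to height and array code. The real split gave 5809 contigs in a fit of tissue alone, the next 1803, with 5 internal samples together. At 1 of 100 chance is unlikely.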
